A study of Homo sapiens with 31 samples.

How the data were processed

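The samples were 31 dual-colour spotted cDNA arrays of MCF7 and MDA-MB-231, established human breast cancer cell lines, in 14 groups: untreated controls of each line, and cells kept in docetaxel for 8, 24 or 48 h at a low dose (4 nM for MCF7, 2 nM for MDA-MB-231) or at 100 nM. Per the labels' protocols, total RNA was amplified by T7 in vitro transcription, the sample was labelled with Cy3 or Cy5, a reference with the other dye, and both were hybridised together. Per the labels, GenePix Pro 4.0 quantified the images of 2 samples; no label says how the other images were quantified. The labels do not state the normalization, the filter on poor spots, the base of the logarithm or which channel is the numerator, and they call the other channel only a reference. A sentence on the design says that untreated control cells served for normalization, without saying how.

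The deposited values were log ratios of the channels of each array, 1 value per spot, with both signs and a median near 0 on every array, so a centring step had been applied that the labels do not name. They were taken as log2 ratios, although neither the base nor the direction is stated. The size of the values does not settle the base: 123 were larger in size than 11.1, the natural log of the largest ratio of 16-bit intensities, but 4 were also larger than its log2 of 16, the largest at 19.4. Arrays of the same line with the sample in different dyes had a median correlation of -0.43 as deposited (92 pairs, -0.87 to -0.21), and those with the sample in the same dye 0.69 (145 pairs), so the sign of the arrays with the sample in Cy3 was turned. Whether the common direction is sample over reference was checked only through the cell lines. The mean of the luminal epithelial list minus that of the mesenchymal list was 2.50 ± 0.27 (SD, n = 19) on MCF7 arrays and -0.04 ± 0.12 (SD, n = 12) on MDA-MB-231 arrays, the order in which these lines are known to differ.

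The value table held 27648 spots. Of these, 17488 were tied to 1 gene symbol, 654 to several and 9506 to none, from the probe table given with the series. Symbols were brought up to date through the Entrez number with the RefSeq gene table of GRCh38.p14, which named 17450 spots; 38 kept the older symbol, and no coordinates were used. Consecutive spots carried the same clone: all 9071 annotated pairs shared their accession, and the median correlation across arrays was 0.983 within annotated pairs, 0.976 within pairs without annotation and 0.0756 between neighbours of different pairs. The mean of the spots was used as the clone's value. Each array was centred on its median. Clones with a value on at least 80% of the arrays (25 of 31) were kept, which left 8129 of 12412 clones; 5493 of these had 1 symbol and covered 4626 genes. With several clones per gene, the clone with the fewest missing values stood for it.

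All 31 arrays were fitted together with limma 3.58.1 in R 4.3.3, with 1 mean per group and a term for the dye of the sample. Because clones lack values on different arrays, the standard errors of the contrasts were taken from each clone's own least squares fit before limma's moderation of the variances. There were 18 comparisons. The mean of the 8, 24 and 48 h groups stood for a dose, single times and 48 h against 8 h were compared separately, and the cell line by dose interaction at 100 nM was tested directly. P-values are 2-sided and were adjusted by Benjamini and Hochberg over all clones tested in a comparison, with a threshold of 0.05. A clone was tested where every group of the comparison had a value, which left 4542 clones for the mean of the 100 nM times in MDA-MB-231.

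Gene lists, 24 in number and holding 874 genes, were tested with limma's camera at its preset correlation of 0.01 between genes and again with the correlation estimated from the residuals; 550 list genes had a clone on the array and 485 passed the filter. They covered p53 targets, G2/M and mitosis, DNA replication and G1/S, tubulins and microtubule regulators, apoptosis regulators, interferon response, NF-kB and inflammatory cytokines, AP-1 and immediate early genes, heat shock and protein folding, the unfolded protein and integrated stress response, oxidative stress (NRF2) genes, metallothioneins, cholesterol and fatty acid synthesis, glycolysis and hypoxia, ribosomal proteins and translation, proteasome and ubiquitin, oxidative phosphorylation, drug transporters and taxane metabolism, oestrogen receptor targets, luminal epithelial markers, mesenchymal and basal B markers, actin cytoskeleton and adhesion, histones, and blood and immune cell markers. The gene lists, the comparisons, the test, the naming rule and the alternatives were written before the data were examined, except for those said here or in the closing section to have been added later. The rule named, among genes past the threshold that lay on the same side of the other group's mean on every array, the 10 largest rises and falls (5 at single times). It also named the 5 genes with the smallest p where none passed, a fixed panel, and up to 4 members of each list described. Clones called outside that rule are named where they were few, after their values were seen.

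Correlation between arrays placed them in 6 sets, called clusters here, which the labels do not name. They came from average linkage, cut at the finest split in which each set held a control of every line in it. That rule fixed the number of clusters. A fit with the cluster as a further term was added after these were seen, and values from it are called cluster-adjusted. Further alternatives were no dye term, no centring, arrays scaled to the same spread, no filter, clones with values on all arrays, arrays of the line concerned, arrays with the sample in Cy5, clones averaged per gene, array weights, the replicate letter as a block, limma's fry in place of camera, and leaving out each array in turn. Leaving out the 6 sparse arrays and removing spots that differed from their pair by more than 1 on the log2 scale, or whose partner had no value, were added later. Other splits of the arrays into groups of the same sizes, at most 100 per comparison, were refitted in the same way, and for 4 comparisons also splits within clusters with the cluster term. To test the clusters on other clones than those they came from, they were drawn again from a random 1 of 2 equal parts of the clones, 100 times.

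On the measured values with known changes added to arrays, the fit recovered 49.3% of clones changed by 1 on the log2 scale and 84.8% of those changed by 2 in the comparison of 100 nM with control in MCF7 (8124 clones), and 89.6% and 98.5% with the cluster term. At 4 nM it recovered 38.8% and 89.4%. In MDA-MB-231 it recovered only 7.46% and 33.3% at 100 nM and 22.4% and 72.7% at 2 nM. Clones given a change were drawn from all 8129, and those that could not be tested count as not recovered. At 100 nM in MDA-MB-231 only 4542 clones were tested, so the shares there understate the recovery among tested clones. Clones called without an added change numbered 1 and 1 in MCF7 at 100 and 4 nM and 2 and 14 in MDA-MB-231 at 100 and 2 nM. With the cluster term they numbered 8, 11, 6 and 44. These were measured values, so clones that docetaxel changed may be among them, and they are not counts of false calls. Simulated values with independent errors gave 3, 4, 0 and 0 in the same order, without the cluster term. The list test was tried only on simulated values with independent errors, at 100 nM in MCF7 (4626 genes). There a shift of 0.3 added to the p53 list was estimated as 0.30 with an adjusted p of 4.0e-04. Of the 23 other lists 0 passed, but the simulated genes were uncorrelated. This does not tell how often lists pass by chance on the measured values. Arrays held values for 8482 to 25727 of the 27648 spots, and the number of arrays limits the precision. Signal over background, flags and images were not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.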

Results

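Transcript levels were measured in MCF7 and MDA-MB-231, established human breast cancer lines with luminal and mesenchymal features respectively, before and after docetaxel, a taxane that stabilises microtubules and holds cells in mitosis. Each of 31 spotted cDNA arrays compared a sample with a reference RNA. MCF7 had 7 control arrays and 2 arrays at each of 8, 24 and 48 h in 100 nM and in 4 nM docetaxel. MDA-MB-231 had 4 control arrays, 1 array at each time in 2 nM, and in 100 nM 1 array at 8 h and 2 each at 24 and 48 h. All controls are labelled 0 h, so time in culture was not separable from time in docetaxel. Nothing says that replicates were separate cultures, so the p-values measure only the spread between these samples.

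The 6 sparse arrays (control replicates A of MCF7 and C of MDA-MB-231, MCF7 100 nM 8 h A, and the A replicates of MDA-MB-231 100 nM at 8, 24 and 48 h) held values for 8482 to 12137 of 27648 spots, and the other 25 arrays for 20415 to 25727. The deposited medians lay between -0.02 and 0.02 in MCF7 controls A to G (-0.0219, 6.3e-04, 0.0039, 0.0232, 0.0091, 0.0106 and -0.0142). They were -0.0218 and 0.0024 for 100 nM at 8 h, 0.0092 and 0.0032 at 24 h and 0.0031 and 0.0211 at 48 h. For 4 nM they were -0.0023 and 0.0023 at 8 h, -0.0012 and 0.0024 at 24 h and -4.0e-04 and 0.0186 at 48 h. MDA-MB-231 controls A to D had 0.0116, 0.0020, -0.0149 and 0.0063. The 2 nM arrays had 5.7e-04, 0.0156 and 0.0089 in the order of time, and the 100 nM arrays -0.0084 at 8 h, -0.0183 and 0.0273 at 24 h and -0.0130 and 0.0141 at 48 h. The base of the logarithm, taken as 2, the centring step and the direction of the ratio are not stated for these columns. Of the 27648 spots, 17488 had 1 gene symbol, 654 several and 9506 none.

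The arrays fell into 6 clusters that cut across the docetaxel groups. Arrays of different groups of a line in the same cluster correlated with a median r of 0.82 across clones (59 pairs), and arrays of the same group in different clusters with 0.49 (29 pairs); the clusters were drawn from these correlations, and clones are not independent replicates. Cluster 1 was the 6 sparse arrays, all with the sample in Cy3. Clusters 2, 3 and 4 held 7, 3 and 7 MCF7 arrays, and clusters 5 and 6 held 5 and 3 MDA-MB-231 arrays. The only other arrays with the sample in Cy3 were 2 in cluster 4. In MDA-MB-231 the dye, the sparse arrays and cluster 1 thus cannot be told apart. The clusters were cut so that each held a control of every line in it, so a cluster term could be fitted. Its value is given for described list calls that it ended or moved by more than 1.5 times, and for some others.

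**Figure D1:**
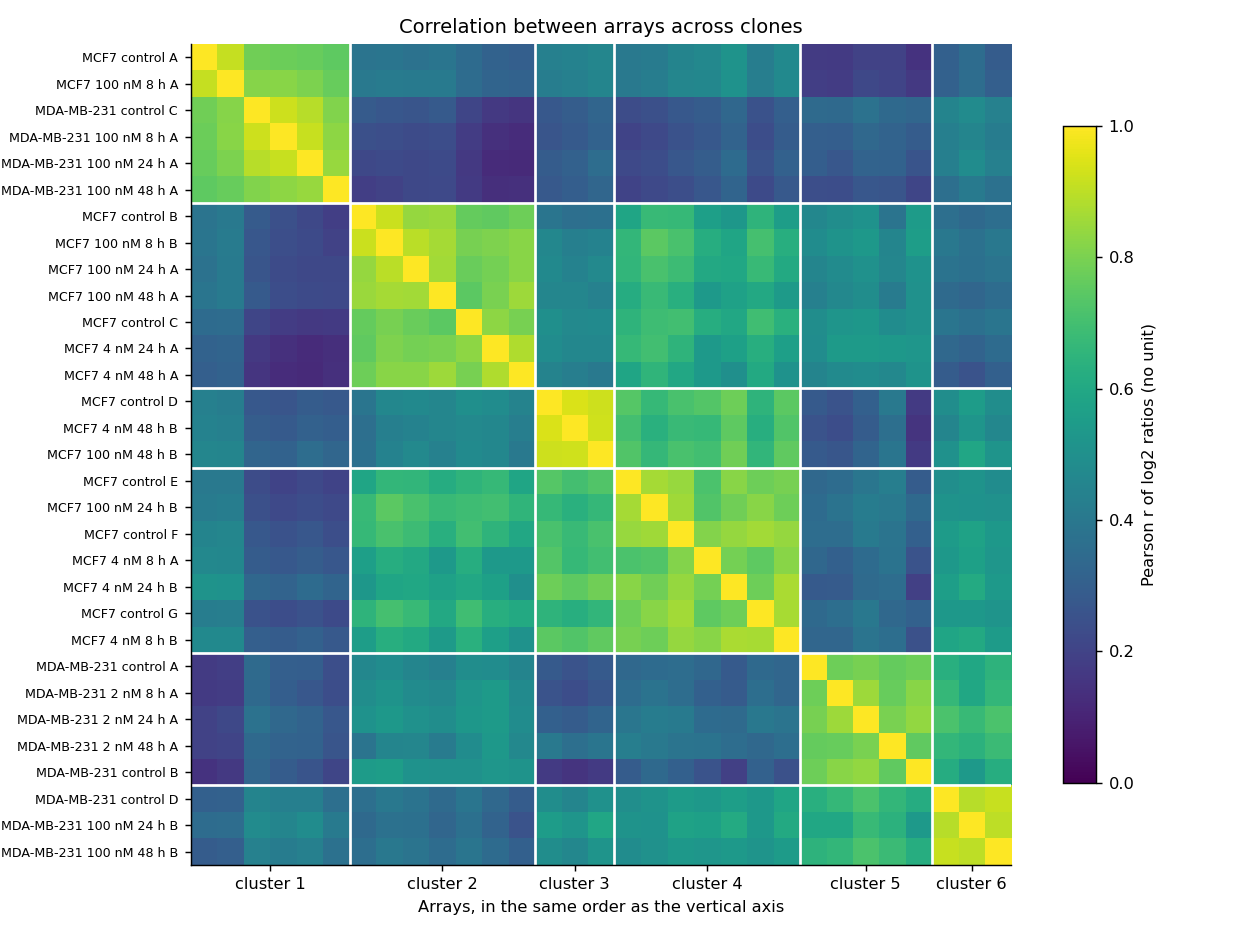
Pearson correlation across clones between the 31 arrays (both axes in the same order, colour from 0 to 1), with white lines between the 6 clusters. Arrays of a cluster correlated with each other whatever their dose, with a median r of 0.82 for different groups of the same line.

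The first comparison, of the untreated lines, shows what the arrays resolve between the lines. TFF1, a secreted trefoil protein whose gene oestrogen receptor activates, was higher in MCF7 than in MDA-MB-231 by 6.62 ± 0.82 (log2, SE; 7 and 4 arrays; adjusted p = 1.5e-05). VCAN, which encodes the matrix proteoglycan versican, was lower by 5.29 ± 0.30 (adjusted p = 2.7e-09), written as -5.29 in MCF7 minus MDA-MB-231. Both held on each of the 7 MCF7 arrays, and the cluster-adjusted values were 3.26 and -4.05. In all, 389 clones were higher and 566 lower in MCF7 of 8129 tested, and with the cluster term 228 and 394 of 5276. Only cluster 1 held both lines, so the cluster term separates line from cluster through it alone. Arrays of different lines in the same cluster had a median r of 0.78 (8 pairs). Arrays of 1 line in different groups and clusters had 0.51 (143 pairs).

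Other genes with large differences came from varied families. Higher in MCF7 were MGST1, a microsomal glutathione transferase (6.90 ± 1.17), FBP1, an enzyme of gluconeogenesis (3.77 ± 0.32), and TSPAN13, a tetraspanin (3.37 ± 0.30). Lower were ANXA1, a phospholipid-binding annexin (-4.66 ± 0.40), TNC, the matrix protein tenascin (-4.15), MMP14, a membrane-bound matrix metalloprotease (-3.85 ± 0.25), and GDA, guanine deaminase (-8.34 ± 1.90, 6 MCF7 arrays). GSTP1, the glutathione transferase P, was lower at -5.00 ± 1.58 with an adjusted p of 0.049, a call that ended with the cluster term (-4.58, adjusted p = 0.24) and without any of 8 of the 11 arrays. The rest of the largest were STARD10, TSPYL5, MOAP1, SPTSSB and FILIP1L on the higher side (3.61 to 4.02) and SLCO2A1, LDHB, CXCL1 and PAX8 on the lower side (-4.36 to -3.76). The SPTSSB call ended with the cluster term (1.78, adjusted p = 0.18). FILIP1L fell to 1.87 (adjusted p = 0.19) without MDA-MB-231 control B, and its call also ended without MCF7 control C, D, E or F. With arrays of the controls only, the calls of FILIP1L, FGG and GSTP1 ended (adjusted p = 0.11, 0.10 and 0.073). FGG, fibrinogen gamma, was 4.04 ± 1.14 but -0.31 with the cluster term, and its call ended without MCF7 control E (3.65) or MDA-MB-231 control A (3.22) or B (2.70).

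Of the panel fixed for the lines, KRT8, a keratin of simple epithelia, was higher by 2.17 ± 0.40 and CD44, a hyaluronan receptor, lower by -2.36 ± 0.53 (adjusted p = 0.0053). CDH1, E-cadherin, was higher by 3.35 ± 0.54 through a clone with which 1 of the other clones disagreed in sign, and its call ended with the cluster term (1.51, adjusted p = 0.12). ESR1, GATA3, VIM, KRT18 and KRT19 did not reach the filter on missing values.

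The luminal epithelial list, markers of the milk-duct lining, was higher in MCF7 with a median of 2.03 over 20 genes (adjusted p = 1.9e-09, and 5.4e-04 with an estimated correlation); 18 lay above 0. Over all genes tested 12 rose and 0 fell, among them FOXA1 (2.16) and EPCAM (2.04), and 14 rose adjusted over the list alone. The sign of the ratios had been checked on this list and the mesenchymal list, so their direction is not independent evidence. The cluster-adjusted luminal median was 0.89 over 15 genes (adjusted p = 0.013 with an estimated correlation). The metallothioneins, small metal-binding proteins, were lower in all 4 genes measured, with a median of -3.04 (adjusted p = 1.9e-08, and 0.0025 with an estimated correlation); MT2A was at -3.56 and MT1X at -3.16. With the cluster term that median was -2.69 and the adjusted p with an estimated correlation 0.076.

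The NF-kB and inflammatory cytokine list was lower in MCF7 with a median of -0.69 over 19 genes (adjusted p = 0.0011, and 0.020 with an estimated correlation). In it 0 rose and 7 fell over all genes tested, and 9 fell adjusted over the list alone; CXCL1, a neutrophil chemokine, was at -3.93, TNFAIP2 at -1.94 and TRAF1 at -1.76. With the cluster term, which rests on cluster 1, its median was -0.06 over 12 genes (adjusted p = 0.94), and TNFAIP2 was at -0.48. Mesenchymal and basal B markers had a median of -0.34 over 33 genes (adjusted p = 9.6e-04, but adjusted p = 0.12 with an estimated correlation): 1 rose, CCN1 (1.05), and 9 fell, including MSN (-3.12) and COL4A2 (-2.74), with 3 and 13 adjusted over the list alone. Its median was -0.51 without MCF7 control D, and -0.77 with the cluster term (adjusted p = 0.22). Ribosomal proteins were higher by a median of 0.43 over 30 genes (adjusted p = 8.9e-06, but adjusted p = 0.089 with an estimated correlation), 28 of them above 0. Of them 7 rose, such as RPL39 (1.10) and RPL35A (1.08), and without MDA-MB-231 control C the median was 0.22 and RPL39 at 0.82 no longer passed. The other 19 lists did not pass, with medians from -0.59 to 0.65. Among them the interferon response list held 6 genes that fell, HLA-B at -1.69, and oestrogen receptor targets held 4 that rose and 1 that fell, with MYB at 2.99 and FHL2 at -2.11.

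**Figure D2:**
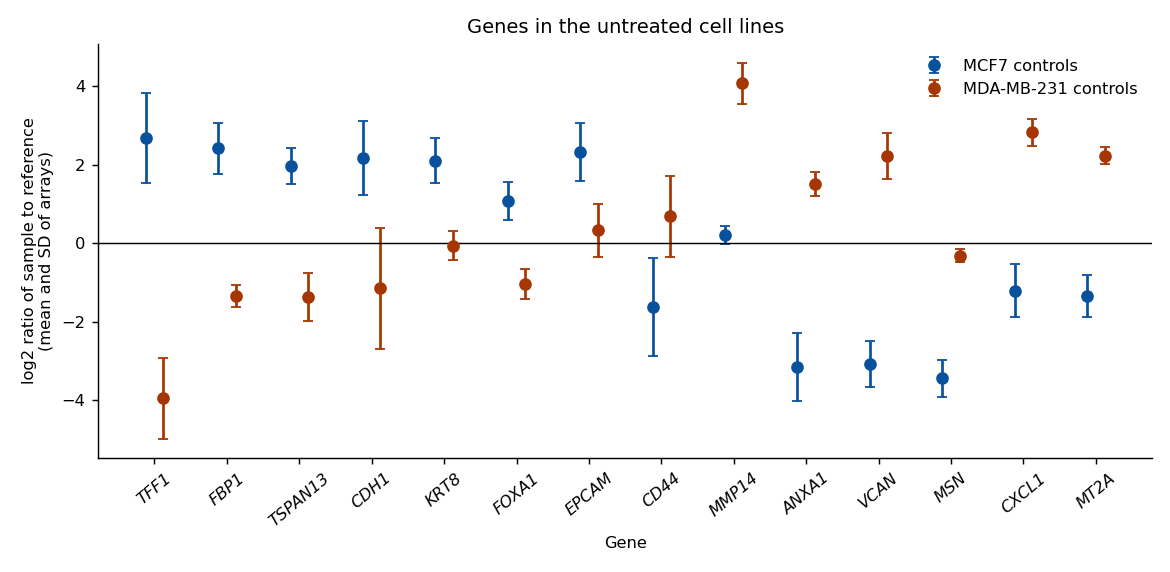
Mean and SD of the log2 ratio of sample to reference in the MCF7 controls and the MDA-MB-231 controls for 14 genes named for this comparison. TFF1 differed by 6.62 and VCAN by -5.29 between the lines.

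The second comparison set MCF7 after 8, 24 and 48 h in 4 nM docetaxel against the controls. CDKN1A, which encodes p21, an inhibitor of cyclin-dependent kinases transcribed by p53, was at 1.32 ± 0.28 (log2, SE; 6 and 7 arrays) and above the control mean on 5 of 6 arrays; the cluster-adjusted value was 1.26. CENPF, a protein of the kinetochore, was at -0.70 ± 0.22 and SMC2, a condensin subunit, at -0.61 ± 0.18, each below the control mean on 6 of 6 arrays. None of them passed over all clones: limma called 0 of 8125 (103 at an unadjusted p under 0.05), and 0 with the cluster term (736 at an unadjusted p under 0.05). Adjusted p was 0.999 for CDKN1A, 0.14 with the cluster term, and 0.0017 (1.60) without MCF7 control replicate D; the count was 2 without 4 nM 8 h replicate A, and 1 without 24 h A or control D or G.

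The p53 target list, genes that p53 switches on after damage or stress, was higher with a median of 0.37 over 21 genes, 20 of them above 0 (adjusted p = 2.5e-10, and 3.2e-05 with an estimated correlation). Over all genes tested 0 rose and adjusted over the list alone 1 did, CDKN1A; PPM1D, a phosphatase, was at 0.42, CCNG1, cyclin G1, at 0.64 and TP53INP1 at 1.12. The cluster-adjusted median was 0.37, with 8 genes up adjusted over the list alone and an adjusted p of 0.026 with an estimated correlation. On single arrays the list lay 0.39 ± 0.43 (SD, n = 6) above controls of the same cluster, on 4 of 6 arrays. Arrays of a cluster share its controls, so such counts and SDs, here and below, are not of independent values. The replication list, genes of S phase entry and DNA synthesis, was lower with a median of -0.19 over 32 genes, 25 below 0 (adjusted p = 6.0e-06, and 0.010 with an estimated correlation); 0 passed singly on either count, with CDC6 at -0.50 and RRM2 at -0.49. With the cluster term its median was -0.19 but the adjusted p with an estimated correlation was 0.083.

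The G2/M list, genes of the spindle and mitosis, had a median of -0.20 over 34 genes, 29 below 0 (adjusted p = 1.0e-05, but adjusted p = 0.37 with an estimated correlation). It had 0 single calls; KNTC1 was at -0.36, TOP2A at -0.52 and KIF23 at -0.47, and without MCF7 control replicate G the list's adjusted p was 0.050 at -0.14. Its median was -0.10 without control E or F and -0.11 without 4 nM 48 h replicate B. Ribosomal proteins had a median of 0.10 over 30 genes, 22 above 0 (adjusted p = 0.0080, but adjusted p = 0.48 with an estimated correlation), with RPL22 at 0.42 and RPS13 at -0.37, a call that ended without control C (0.07) or 4 nM 8 h B (0.06), 24 h A (0.10) or 48 h A (0.07); without 48 h B the median was 0.17. The other 20 lists did not pass, with medians from -0.09 to 0.15. Further genes with a small p were CSE1L, an export factor (-0.56), and LRPAP1, a receptor chaperone (-0.55), whose other clone had the opposite sign. In the fixed panel PLK1 was at -0.30, AURKA at -0.19, MDM2 at 0.38, STMN1 at -0.18, CDC20 at -0.01, BIRC5 at -0.03 and TUBB at -0.02.

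At 100 nM in MCF7, the third comparison, the genes with the smallest p included replication genes and others named below. CDC6, which loads the replicative helicase at origins, was at -0.87 ± 0.20 (log2, SE; 6 and 7 arrays) and below the control mean on 6 of 6 arrays. DTL, a substrate receptor of a ubiquitin ligase active in S phase, was at -0.65 ± 0.16 (6 of 6 arrays), and RRM2, a subunit of ribonucleotide reductase, at -0.68 ± 0.20 (5 of 6). PLK1 and AURKA, kinases of mitosis, were at 0.91 ± 0.30 and 0.75 ± 0.27, each above the control mean on 5 of 6 arrays. None passed over all clones: limma called 0 of 8124 (175 at an unadjusted p under 0.05), and 0 with the cluster term (413 at an unadjusted p under 0.05). Without MCF7 100 nM 8 h replicate B the count was 19, all higher, and without 24 h B and 48 h B it was 3 and 1, all lower.

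The replication list was lower with a median of -0.26 over 32 genes, 24 below 0 (adjusted p = 1.1e-09, and 2.8e-04 with an estimated correlation). Over all genes tested 0 fell, and adjusted over the list alone 2 did, CDC6 and RRM2; PCNA, the sliding clamp, was at -0.86 and MCM4, a helicase subunit, at -0.64. The cluster-adjusted median was -0.26 as well, with 9 down adjusted over the list alone and an adjusted p of 0.0017 with an estimated correlation. On single arrays the list lay 0 times above and 6 times below controls of the same cluster (-0.31 ± 0.21, SD, n = 6), and without 100 nM 8 h replicate B the median was -0.43.

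The p53 targets had a median of 0.21 over 21 genes, 18 above 0 (adjusted p = 0.0015, but adjusted p = 0.064 with an estimated correlation). They had 0 single calls on either count; CDKN1A was at 0.69, BBC3, the cell death activator PUMA, at 0.84 on the same side of the control mean on 6 of 6 arrays, and CCNG1 at 0.61. Without MCF7 100 nM 48 h replicate A the adjusted p was 0.099 at 0.15, and without 48 h B the median was 0.32. The G2/M list had a median of 0.21 over 34 genes, 22 above 0 (adjusted p = 0.047, but adjusted p = 0.68 with an estimated correlation), with CENPE at 0.66 and TOP2A, a topoisomerase, at -0.59. That call ended without any of MCF7 controls A (0.13), B (0.28), C (0.22) and D (0.10), 100 nM 8 h B (0.10), 24 h B (0.26) and 48 h B (0.10).

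Apoptosis regulators had a median of 0.17 over 27 genes, 19 above 0 (adjusted p = 0.037, but adjusted p = 0.064 with an estimated correlation), with FADD at 0.51, XIAP at 0.49 and BID at 0.63. Interferon response genes had 0.12 over 31 genes, 25 above 0 (adjusted p = 0.037, but adjusted p = 0.47 with an estimated correlation), with SP100 at 0.38, IFI44 at 0.97 and OAS2 at 0.81. Neither had single calls. Both calls ended without MCF7 control B (0.14 and 0.16), control C (0.17 and 0.15), or 100 nM 8 h A (0.18 and 0.12), 8 h B (0.15 and 0.16), 24 h B (0.16 and 0.17) or 48 h A (0.13 and 0.06). The first also ended without control A (0.08) or 48 h B (0.22) and the second without control D (0.12), and without 48 h B the second had a median of 0.22. The other 19 lists did not pass, with medians from -0.11 to 0.19. The remaining genes with the smallest p were TSPAN7, a tetraspanin (-2.28 ± 0.52, 4 arrays), and POLR3K, a subunit of RNA polymerase III (-0.96 ± 0.27). In the fixed panel CDC20 was at 0.55, STMN1 at 0.16, BIRC5 at -0.09 and TUBB at -0.03. MDM2 was at 0.41, but at -0.13 with the sample in Cy5 only, -0.12 with the cluster term, -0.17 without the sparse arrays and -0.03 without 8 h A.

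Setting 100 nM against 4 nM in MCF7 compared the doses directly. PLK1 was higher at 100 nM by 1.21 ± 0.31 (log2, SE; 6 and 6 arrays) and AURKA by 0.95 ± 0.28, each on 5 of 6 arrays. Over all clones they did not pass (adjusted p = 0.88): limma called 0 of 8120 (327 at an unadjusted p under 0.05), 0 with the cluster term (957 at an unadjusted p under 0.05), and 13 without MCF7 100 nM 8 h replicate B. TSPAN7 was at -2.31 (-2.73, adjusted p = 0.041, without 4 nM 8 h replicate B), REG3A, a secreted lectin, at -0.54 and PUS3, a pseudouridine synthase, at 0.84.

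The G2/M list was higher at 100 nM with a median of 0.40 over 34 genes, 27 above 0 (adjusted p = 9.0e-07, but adjusted p = 0.42 with an estimated correlation). Adjusted over the list alone PLK1 and AURKA rose, against 0 over all genes tested; CENPE was at 0.75 and CENPF at 0.64. With the cluster term 31 of 34 lay above 0, the median was 0.50 and 15 rose adjusted over the list alone, with an adjusted p of 0.30 with an estimated correlation. Within pairs of arrays of the same cluster and time, the median of 100 nM minus 4 nM was 0.54 and 0.73 at 24 h, and -0.50 and 0.70 at 48 h. Without MCF7 100 nM 48 h replicate B the list's median was 0.26 and its adjusted p 0.092. The p53 list was lower at 100 nM in all 4 such pairs (-0.50, -0.28, -0.23 and -0.30) and passed only with the cluster term (-0.26, adjusted p = 0.028, but adjusted p = 0.76 with an estimated correlation). The other 23 lists did not pass, with medians from -0.16 to 0.15.

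Across 8120 clones, which are not independent replicates, the effects of 100 nM and 4 nM on MCF7 had a correlation of 0.04 and a covariance of 0.0025. Simulated unchanged groups against the same controls gave 0.065 (0.029 to 0.12 over 50 draws) and 0.0036. With the cluster differences simulated as well they gave -0.079 (-0.15 to -0.030) and -0.0054. With the cluster term the correlation was 0.21 and the covariance 0.0104, against -6.0e-04 and -3.3e-05 in simulations with cluster differences. The simulated groups were drawn around the means of the measured controls. Control error, which both doses share, thus largely cancelled in them. Observed values above the simulated ones therefore cannot tell a shared effect of the doses from shared controls. With the controls split between the doses and no cluster term the correlation turned to -0.41 (-0.68 to 0.09 over 70 splits) and the covariance to -0.048. No clone was called at either dose, so there were no calls to compare.

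**Figure D3:**
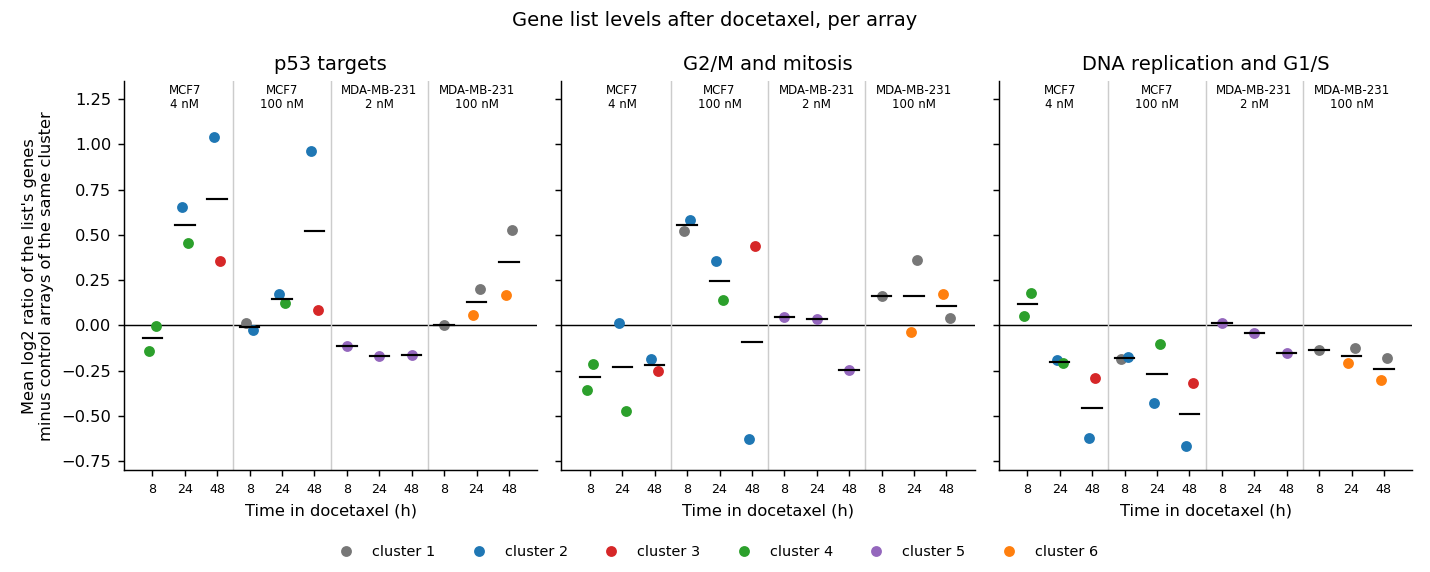
Mean log2 ratio of the p53, G2/M and replication lists on each docetaxel array minus the control arrays of the same cluster; points are arrays, coloured by cluster, and bars are means of a group. In MCF7 the replication list lay below controls on 6 of 6 arrays at 100 nM, and the p53 list reached 1.04 on an array at 4 nM for 48 h.

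The time course in MCF7 set each time against the 0 h controls, and 48 h against 8 h. CDKN1A was at -0.37, 0.01 and 2.44 ± 0.41 after 8, 24 and 48 h in 100 nM, and at 0.08, 1.45 and 2.43 ± 0.41 in 4 nM (2 arrays each, 7 controls). PLK1 was at 1.06, 0.97 and 0.68 in 100 nM and at -0.46, -0.11 and -0.33 in 4 nM, but at -0.34 at 48 h in 100 nM without replicate B. In 4 nM it was at 0.30 at 8 h without B and 0.15 at 24 h without A. AURKA was at 0.89, 1.39 and -0.02 (0.62 without replicate A) in 100 nM, and at 0.10, 0.00 and -0.68 in 4 nM. CDKN1A at 48 h in 100 and 4 nM did not pass over all clones (adjusted p = 0.10, 0.11), nor cluster-adjusted (1.98, 1.96). It passed without control D (2.74, 2.73), the only control in the cluster of 48 h B.

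At 8 h in 100 nM the G2/M list was up with a median of 0.43 over 34 genes (adjusted p = 6.7e-06, but adjusted p = 0.72 with an estimated correlation, and 0.54 and 0.048 with the cluster term), with CENPE, a kinetochore motor, at 1.29 and CDC25C, a phosphatase that starts mitosis, at 0.86, each with a value on 1 of the 8 h arrays. Without MCF7 100 nM 8 h replicate B it was 0.12 (adjusted p = 0.57). TSPAN7 fell by 6.06 ± 0.83 (adjusted p = 0.028), with a value on 1 of the 8 h arrays, whose spots disagreed and which was assumed to vary like the other groups. That 1 call of 8124 became 56, all higher, without replicate B, 2 without replicate A, and 0 without MCF7 control B, C, D, E or F. At 8 h in 4 nM none of the 24 lists passed, and limma called 0 of 8125 clones (395 at an unadjusted p under 0.05) but 38 without MCF7 control G, 6 without 8 h replicate A and 8 without replicate B. The smallest p there belonged to TWIST1, a transcription factor of mesenchymal cells (-1.68), RGS2, a regulator of G protein signalling (-3.10), GARRE1 (-1.26), LARP6 (-1.95) and ARMCX2 (-1.74); without control G all 5 passed, RGS2 at -4.27 and TWIST1 at -2.15. Without replicate A RGS2 was at -1.15, LARP6 at -0.44 and ARMCX2 at -0.85.

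At 24 h in 100 nM the G2/M median was 0.41 (adjusted p = 5.5e-08, but adjusted p = 0.26 with an estimated correlation), with PTTG1, securin, at 1.01 and CCNB2, a B-type cyclin, at 0.88 while TOP2A was at -1.17; without 24 h replicate B it was 0.47 with an adjusted p of 0.067. The replication median was -0.15 (adjusted p = 0.0020, but adjusted p = 0.26 with an estimated correlation), and its call ended without control B (-0.10), 24 h A (-0.09) or 24 h B (-0.14). In 4 nM the p53 list was up by 0.48 (adjusted p = 3.6e-12, and 3.6e-06 with an estimated correlation; 0.47 and 0.074 with the cluster term), and CDKN1A and PPM1D rose adjusted over the list alone, against 0 over all genes tested. Its median was 0.76 without replicate B. Passing only with the preset correlation in 4 nM were drug transporters (0.31, adjusted p = 0.11 with an estimated correlation; 0.20 and 0.31 with the cluster term) and ribosomal (0.15), proteasome (-0.08, and -0.13 with the cluster term) and replication genes (-0.13), each of these 3 with an adjusted p of 0.46 with an estimated correlation; the replication call ended without control B or C or either 24 h array (-0.09 to -0.03), and its median was -0.20 without control D. Clone by clone, limma called 0 at 24 h at either dose (99 in 100 nM and 76 in 4 nM at an unadjusted p under 0.05), against 9 without 100 nM 24 h B, and 2 and 4 without 4 nM 24 h A and B. Small p-values were those of AURKA, HSPB1P2 (0.88), ADGRG6 (-0.96), TOP2A and PLAU (-5.04, but 0.41 without replicate A and -10.50 without B) in 100 nM and of CD69 (-4.61, -2.07 without replicate A and -7.15 without B), CDKN1A, PPM1D, FHL3 (-0.73) and POLR1F (-0.68) in 4 nM.

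At 48 h in either dose the replication list was lower and the p53 list higher than in the 0 h controls. Time in culture was not tested apart from docetaxel. Replication genes had a median of -0.61 in 100 nM (adjusted p = 9.3e-19, and 2.3e-08 with an estimated correlation) and -0.47 in 4 nM (3.1e-16 and 3.1e-07); 7 and 2 fell adjusted over the list alone, against 0 over all genes tested. CDC6 was at -1.35 and -1.08, RRM2 at -1.30 and -1.26, and PRIM1, a primase subunit, at -1.06 in 100 nM. The p53 list was at 0.45 in 100 nM (adjusted p = 1.9e-09, and 6.5e-05 with an estimated correlation) and 0.80 in 4 nM (4.6e-13 and 8.9e-07); CDKN1A rose adjusted over the list alone at 100 nM, and CDKN1A, PPM1D, TP53INP1 and CCNG1 did at 4 nM. Without 100 nM 48 h replicate A the 100 nM p53 median was 0.17 (adjusted p = 0.18), without its replicate B 0.80, and without 4 nM 48 h A that of 4 nM was 0.53. With the cluster term the replication medians were -0.48 and -0.52 and the p53 medians 0.46 and 0.64, all 4 past the threshold with an estimated correlation (at most 0.0030).

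The G2/M list at 48 h was at -0.41 in 100 nM (adjusted p = 2.6e-06, but adjusted p = 0.18 with an estimated correlation), with CDK1, the mitotic kinase, at -1.63, and at 8.3e-04 without replicate A and -0.67 without replicate B. In 4 nM it was at -0.53 (adjusted p = 3.6e-11, and 0.047 with an estimated correlation, but 0.24 with the cluster term as well), with KNTC1 at -0.78 and BUB1B, a checkpoint kinase, at -0.89, and at -0.27 without replicate B. Tubulins and microtubule regulators, the targets of docetaxel and their partners, were at -0.22 in 4 nM (adjusted p = 1.2e-04, and 0.013 with an estimated correlation, but 0.061 with the cluster term as well), with TUBA1A at -0.56 and TUBB4B at -0.76. Apoptosis regulators were at 0.18 in 100 nM (adjusted p = 0.011, and 0.037 with an estimated correlation), with BAX, a pore former of mitochondria, at 0.90. Passing only with the preset correlation were interferon (0.26), AP-1 (0.45) and ribosomal (0.25) genes in 100 nM and AP-1 (0.41), heat shock (-0.32) and proteasome (-0.09) genes in 4 nM (adjusted p = 0.17 to 0.42 with an estimated correlation). The cluster term ended the AP-1 call in 100 nM (0.27, adjusted p = 0.080) and the proteasome call in 4 nM (-0.06, 0.10), and the heat shock median in 4 nM was -0.10 with it. Over all clones limma called 0 at either dose (237 in 100 nM and 230 in 4 nM at an unadjusted p under 0.05), 4 and 6 without MCF7 control D, and 4 and 3 without the B replicates. Other small p-values were those of XPO1 (-0.75) and CD7 (-0.95) in 100 nM and of SOCS1 (1.09), RPS27L (1.58) and PPM1D (0.82) in 4 nM.

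Between 8 and 48 h the replication list fell by a median of 0.55 in 100 nM (adjusted p = 1.4e-08, and 0.0013 with an estimated correlation) and by 0.70 in 4 nM (7.6e-09 and 6.9e-04), and the p53 list rose by 0.51 (1.8e-05 and 0.0093) and 0.78 (9.2e-07 and 0.0016). The G2/M list fell by 0.87 in 100 nM (adjusted p = 5.2e-13, and 0.027 with an estimated correlation), with CDC25C, which had a value on 1 of the 8 h arrays, at -1.32 and CDK1 at -1.75. In 4 nM the G2/M list was at -0.44 (adjusted p = 1.7e-04, but adjusted p = 0.31 with an estimated correlation), a call that the cluster term ended (-0.11, adjusted p = 0.56). Without 100 nM 48 h replicate A the p53 and G2/M medians in 100 nM were 0.04 and -0.36 (adjusted p = 0.36 and 0.20), and without its replicate B the p53 median was 0.82. Without 4 nM 48 h replicate B the G2/M median in 4 nM was -0.36 (adjusted p = 0.082), and without A -0.73. Tubulins were at -0.41 in 4 nM (adjusted p = 4.9e-04, and 0.029 with an estimated correlation), and this call too ended with the cluster term (-0.24, adjusted p = 0.096). Passing only with the preset correlation were AP-1 (0.34) and ribosomal (0.30) genes in 100 nM and AP-1 (0.79), heat shock (-0.49), metallothionein (-0.84), proteasome (-0.24), mesenchymal (0.26) and histone (1.54) genes in 4 nM (adjusted p = 0.18 to 0.49 with an estimated correlation). The calls in 4 nM that ended with the cluster term were those of AP-1 (0.16), heat shock (-0.18), metallothionein (-0.38), proteasome (-0.08) and mesenchymal (0.18) genes (adjusted p = 0.096 to 0.56), and the histone median was 0.75. In clone tests limma called 0 in either dose (236 in 100 nM and 615 in 4 nM at an unadjusted p under 0.05), against 23 and 1 without 100 nM 8 h B and 48 h B, and 5, 7 and 2 without 4 nM 8 h A, 8 h B and 48 h B. The smallest p belonged to TSPAN7 (6.54), CDKN1A (2.81), RPS27L (2.03), HAUS1 (-1.09) and AQP3 (2.01) in 100 nM and to BNIP3L (2.34), GARRE1 (1.61), LARP6 (2.59), CDKN1A (2.34) and CDCA7 (-2.07) in 4 nM.

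**Figure D4:**
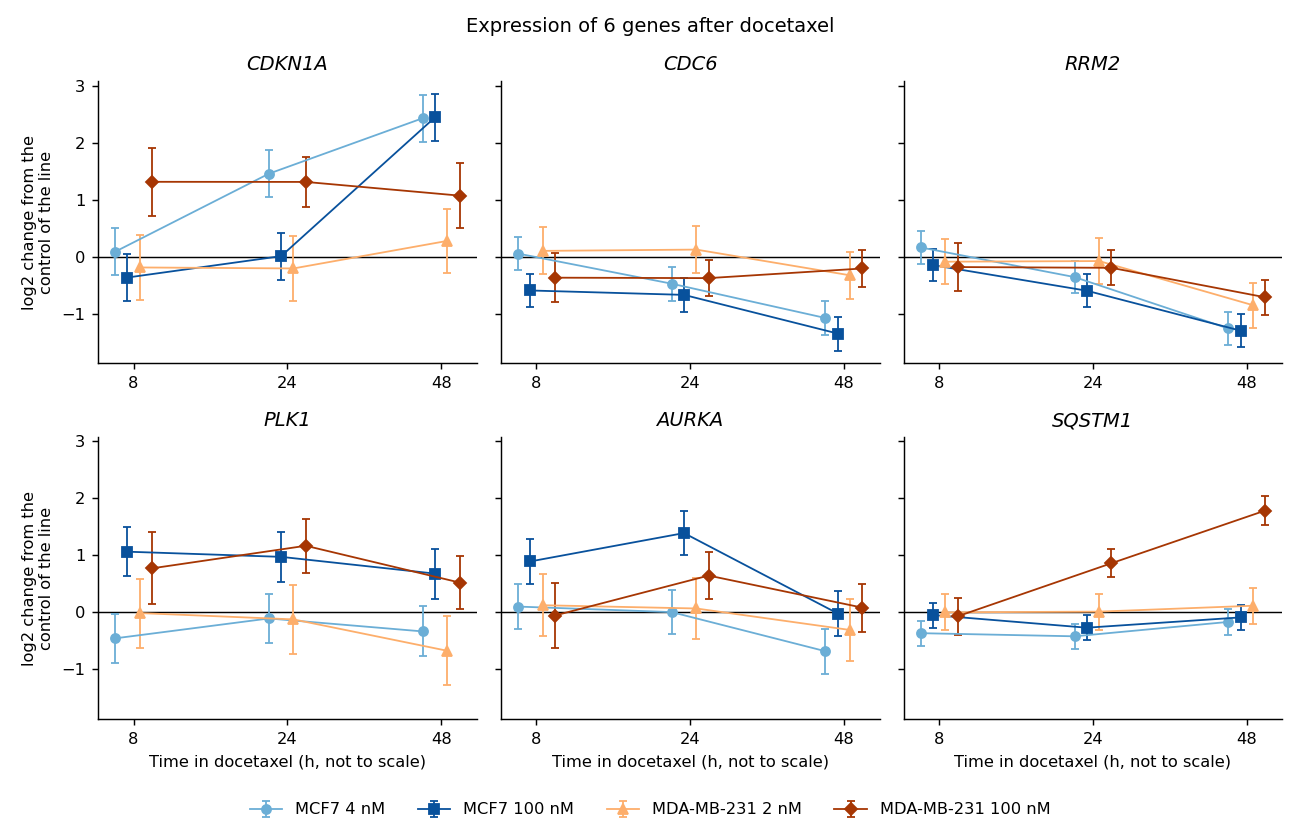
Change from the control of the line (log2) of CDKN1A, CDC6, RRM2, PLK1, AURKA and SQSTM1 after 8, 24 and 48 h of docetaxel, with lines joining times of the same dose and bars for the SE. In MCF7 CDKN1A reached 2.44 in 100 nM and 2.43 in 4 nM at 48 h, and in MDA-MB-231 SQSTM1 reached 1.79 in 100 nM.

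In MDA-MB-231, whose p53 gene is mutated, 100 nM was compared with control over the 3 times. SQSTM1, an autophagy receptor, was at 0.86 ± 0.21 (log2, SE; 5 and 3 arrays) and CDKN1A at 1.23 ± 0.37 (4 and 4 arrays), each above the control mean on every docetaxel array with a value. PLK1 was at 0.82 ± 0.39 (5 of 5 arrays) and TOP2A at -0.65. None of these passed (adjusted p = 0.68 to 0.94). limma called 1 of 4542 clones (173 at an unadjusted p under 0.05), a clone without a gene symbol at 2.07, 0 with the cluster term and 2 without 48 h replicate B. PAX8, a transcription factor, was at 1.33, LIF, a cytokine, at 1.28, PXDN, a peroxidase of the matrix, at -0.95 and ANKRD13D at 0.99. In the panel CDC20 was at 0.63, AURKA at 0.22, TUBB at 0.21, BIRC5 at 0.10 and STMN1 at 0.04.

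Of the lists, 4 passed with the preset correlation and 0 with an estimated correlation, and none had a single call on either count. Replication genes had a median of -0.24 over 29 genes, 21 below 0 (adjusted p = 0.0023, but adjusted p = 0.32 with an estimated correlation), with PCNA at -0.76, MCM7 at -0.77 and LIG1, a ligase, at 0.54. On 5 of 5 arrays they lay below controls of their cluster (-0.19 ± 0.07, SD), and the cluster-adjusted median was -0.23. The only controls there were replicate C in cluster 1 and replicate D in cluster 6, so the 5 differences are not independent. Their SD leaves out the spread between controls. The cluster term ended the other 3 calls described next: heat shock at -0.15, interferon at 0.18 (adjusted p = 0.17 each) and proteasome at -0.02 (0.35). Heat shock genes, chaperones of protein folding, had -0.37 over 17 genes, 15 below 0 (adjusted p = 0.0023, but adjusted p = 0.48 with an estimated correlation), with HSP90AB1 at -0.62 and HSPA4 at -0.48. Interferon response genes had 0.30 over 18 genes, 16 above 0 (adjusted p = 0.017, but adjusted p = 0.48 with an estimated correlation), with OAS1, an antiviral enzyme, at 0.90 and MX1 at 0.40. Proteasome genes had -0.13 over 25 genes, 19 below 0 (adjusted p = 0.017, but adjusted p = 0.67 with an estimated correlation), with PSMB4 at -0.58. The interferon call ended without MDA-MB-231 control B (0.21) or C (0.34) or 100 nM 24 h B or 48 h B (0.32 each), and the proteasome call without control B (-0.02) or D (-0.16) or 24 h B (-0.14); the proteasome median was -0.30 without control C. The other 19 lists did not pass, with medians from -0.09 to 0.42; LIF rose adjusted over the NF-kB list alone.

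At 48 h in 100 nM the NF-kB and inflammatory cytokine list was up in MDA-MB-231 with a median of 0.67 over 19 genes (2 and 4 arrays, adjusted p = 2.0e-04, and 0.0098 with an estimated correlation), and with the cluster term 0.74 and 1.8e-06. Of the 2 docetaxel arrays, replicate A was sparse, with 69.1% of its spots missing. At single times only the p53, G2/M and replication lists were refitted in the further alternatives or without single arrays, so this list was not. SOD2, the mitochondrial superoxide dismutase, was at 1.75 ± 0.35 and NFKB2, an NF-kB subunit, at 1.53 ± 0.32 with a value on 1 docetaxel and 3 control arrays; these 2 rose adjusted over the list alone and 0 over all genes tested. Over all clones limma called 4 of 8126 higher: SQSTM1 (1.79 ± 0.25, adjusted p = 0.0028, on 2 of 2 arrays, but 1.68, adjusted p = 0.11, without replicate A), and HMOX1, haem oxygenase (3.61, adjusted p = 7.3e-04), PLEK2 (2.08) and PXK (5.46), each with a value on 1 docetaxel array. Their p-values assume that this array varies like the other groups. The PXK clone was not tested with spots that disagreed or stood alone removed. PLEK2 no longer passed without MDA-MB-231 control B (2.00) or D (1.99). With arrays of MDA-MB-231 only, the calls of SQSTM1, PLEK2 (adjusted p = 0.91 each) and HMOX1 (0.34) ended, and with the sample in Cy5 only that of SQSTM1 did (1.73, adjusted p = 0.32). The count was 9 with the cluster term and 86 without MDA-MB-231 100 nM 48 h replicate B. Interferon genes were at 0.42 (adjusted p = 2.0e-04, but adjusted p = 0.064 with an estimated correlation; OAS1 1.45, MX1 0.95), apoptosis regulators at 0.33 and NRF2 genes at 0.14 (each 0.027, but adjusted p = 0.064 with an estimated correlation), while heat shock (-0.26, and -0.07 with the cluster term) and proteasome (-0.21) genes were lower (adjusted p = 0.33 with an estimated correlation). Replication genes were at -0.30 (adjusted p = 0.0017, but adjusted p = 0.066 with an estimated correlation; RFC3 -1.03), and -0.52 with an adjusted p of 0.20 without replicate B. At 24 h limma called 4 of 8129 clones higher, MAP3K1, a signalling kinase (3.31 ± 0.40, adjusted p = 0.0068), IL2RB (2.58), CRAT (2.04), each on 1 docetaxel array under the same assumption, and a clone without a symbol. Without replicate B the count was 7, and without MDA-MB-231 control A or B it was 2, CRAT at 1.95 and 2.07 no longer passing. With arrays of MDA-MB-231 only the 3 named calls ended (adjusted p = 0.71 each), as they did with arrays scaled to the same spread (0.082, 0.052 and 0.082). With spots that disagreed removed, the 24 h clones were not tested. Heat shock genes passed at 24 h with the preset but not with an estimated correlation (HSPH1 -0.87, HSF1 -0.54, HSP90AB1 -0.79, but BAG3 0.54). CDC20 was at 1.43 and CDKN1A at 1.31 at that time, and replication genes at -0.21 (adjusted p = 0.030, but adjusted p = 0.76 with an estimated correlation), a call that ended without control D (-0.17) or 24 h A (-0.19).

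At 2 nM in MDA-MB-231, with 1 array at each time, limma called 1 clone of 7973 (154 at an unadjusted p under 0.05). MYCBP2, a ubiquitin ligase, fell by 5.77 ± 0.36 (log2, SE; 3 and 3 arrays; adjusted p = 8.7e-08), on 3 of 3 arrays, but the call ended with arrays of MDA-MB-231 only (-5.64, adjusted p = 0.11). It was not tested with spots that disagreed removed. CDKN1A was at -0.04 ± 0.39, PLK1 at -0.27, AURKA at -0.04, CDC20 at -0.50, TOP2A at 0.07, MDM2 at -0.43, STMN1 at 0.41, BIRC5 at -0.30 and TUBB at -0.32. The count was 20 with the cluster term (13 rose and 7 fell), and 4 and 2 without MDA-MB-231 control B and D. Ribosomal proteins had a median of 0.18 over 30 genes, 24 above 0 (adjusted p = 0.0019, but adjusted p = 0.86 with an estimated correlation), with RPL35 at 0.60 and RPL18 at 0.31; without MDA-MB-231 control C the median was 0.10 and the call ended, as it did with the cluster term (0.08, adjusted p = 0.18). The other 23 lists did not pass, with medians from -0.18 to 0.16, but adjusted over the list alone MAD2L1, a spindle checkpoint protein, rose by 1.79 ± 0.36 in the G2/M list (adjusted p = 0.097 over all genes tested).

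Between 100 nM and 2 nM in MDA-MB-231, 6 clones of 4469 were higher and 0 lower (444 at an unadjusted p under 0.05). MARCKSL1, which binds actin and calmodulin, was higher by 2.68 ± 0.34 (log2, SE; 5 and 3 arrays; adjusted p = 5.2e-04) and IPO13, a nuclear import receptor, by 3.03 ± 0.58 (adjusted p = 0.041); with the cluster term they were at 3.12 and 2.47, the last with an adjusted p of 0.33. With arrays of MDA-MB-231 only, both calls ended (2.51, adjusted p = 0.30, and 2.62, adjusted p = 0.067), and with clones of a gene averaged that of IPO13 did (1.61, adjusted p = 0.12). Neither was tested with spots that disagreed removed, and the IPO13 call ended without any of the 24 and 48 h arrays at 100 nM (2.98 to 3.18). Outside the naming rule, and chosen after their values were seen, F2RL2 (3.27), TRIB2 (2.55) and SEC31A (1.21) also passed. The count was 4 with the cluster term, 3 higher and 1 lower, and 2 without MDA-MB-231 100 nM 48 h A; the doses shared no cluster. Interferon response genes had a median of 0.48 over 18 genes (adjusted p = 0.025, but adjusted p = 0.58 with an estimated correlation), with OAS1 at 1.04, and HLA-G at 1.05 but -0.73 with the cluster term; the call ended without 100 nM 24 h B (0.55) or 48 h B (0.50), and with the cluster term (0.17, adjusted p = 0.57). Proteasome genes had -0.29 over 25 genes (adjusted p = 0.0023, but adjusted p = 0.58 with an estimated correlation), with PSMB4 at -0.97, and -0.02 with the cluster term (adjusted p = 0.51); neither list had a single call, and the other 21 did not pass, with medians from -0.29 to 0.69.

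Whether the change after 100 nM differed between the lines was tested as MCF7 minus MDA-MB-231. SQSTM1 had a difference of -0.99 ± 0.26 (log2, SE), LIF of -1.35 and PAX8 of -1.29, the genes higher in docetaxel in MDA-MB-231, and FGF19, a growth factor, of 0.99; none passed (adjusted p = 0.99). MARCKSL1 was at -1.19. limma called 1 of 4542 clones (87 at an unadjusted p under 0.05), without a symbol, at -2.10, and 0 with the cluster term. That count was 0 without MCF7 100 nM 8 h B or MDA-MB-231 100 nM 24 h B or 48 h B, and 2 without MCF7 100 nM 24 h B. Heat shock genes had a median difference of 0.47 over 17 genes, 14 above 0 (adjusted p = 0.019, but adjusted p = 0.91 with an estimated correlation), with HSPA4 at 0.62 and HSPH1 at 0.76. The cluster term left a difference of 0.13 and the call ended (adjusted p = 0.63). It also ended without any of MCF7 controls D (0.21) and E (0.37), MDA-MB-231 controls A (0.38) and D (0.40), and the A replicates of MDA-MB-231 100 nM at 24 h (0.45) and 48 h (0.38). The other 22 lists did not pass, with medians from -0.38 to 0.20.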

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

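Chosen only after their results were seen were the tests of dye and sparse arrays for the clusters, the splits within clusters for all lists but G2/M between the doses, the p53 list at low dose between the lines, the G2/M list between 48 and 8 h with the cluster term, and every value with the cluster term, without the 6 sparse arrays or with disagreeing spots removed.

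Of 71 groups of values tested for 1 far from the others, 9 had one, in controls with 4 to 7 values. Chance flags about 1 in 20 groups. Among MCF7 controls, replicate A lacked 57.7% of its spots (the others 6.98 to 20.3%) and had a median absolute deviation of 1.01 (the others 0.40 to 0.61). Replicate G had GDA at -13.82 (the others -4.07 to -3.13). Replicate D had MMP14 at 0.65 (0.06 to 0.27), PAX8 at -0.13 (0.29 to 0.37) and CDKN1A at 1.39 (-0.97 to -0.04). Among MDA-MB-231 controls, CD44 was 2.22 in replicate C (0.01 to 0.26), CDC20 0.56 in B (1.496 to 1.635) and AURKA 0.24 in D (0.41 to 0.43).

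A difference between groups, tested as such, marked 9 further results. An unnamed clone differed by -2.10 between the lines in its response to 100 nM, MCF7 minus MDA-MB-231. In the response to the low dose MYCBP2 differed by 5.57 and the p53 list by a median of 0.42. Between 48 and 8 h in 100 nM the p53 list differed by 0.51, the G2/M list by -0.87 and the replication list by -0.55. Without 48 h replicate A the first 2 no longer passed (0.04, adjusted p = 0.36, and -0.36, adjusted p = 0.20). In 4 nM the p53 list differed by 0.78, the replication list by -0.70 and the tubulin list by -0.41, the last no longer passing with the cluster term (-0.24, adjusted p = 0.096). Lists were kept here only where they passed with the preset and with an estimated correlation, a narrowing chosen after the values were seen. It left out the heat shock list between the lines at 100 nM (0.47, adjusted p = 0.91 with an estimated correlation) and 3 lists at the low dose: G2/M (-0.15, 0.86), cholesterol synthesis (0.39, 0.37) and proteasome (-0.12, 0.86). Between 48 and 8 h it left out the AP-1 and ribosomal lists in 100 nM. In 4 nM it left out the G2/M, AP-1, heat shock, metallothionein, proteasome, mesenchymal and histone lists.

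The first pattern weighed is that arrays correlated by cluster more than by docetaxel group. The clusters came from the same correlations, so the clones were divided at random into 2 equal parts, 100 times. Clusters drawn again from 1 part (6 to 9 of them) differed in median r on the other part by 0.35 (0.31 to 0.38). The dye of the sample as the whole cause is argued against by a difference of 0.199 (0.17 to 0.22) with the sample in Cy5 only, and the 6 sparse arrays as the whole cause by 0.182 (0.16 to 0.20) without them, though either may account for part of it. All 6 sparse arrays had the sample in Cy3, so both settings leave them out and are not separate tests. A batch of RNA, labelling or printing per cluster stays open, since the labels name none, and no biological explanation was tested.

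The second pattern is that the G2/M list lay higher at 100 nM than at 4 nM in MCF7, by a median of 0.40. The sparse arrays and the dye are argued against, since the median was 0.51 without those arrays and 0.48 with the sample in Cy5 only. Both settings leave out the 6 sparse arrays. Splits within the clusters gave a median as large in 9 of 80, the real one counted (0.50, highest other 0.71), so chance among arrays of the same clusters cannot be excluded. A dose effect, in which cells held in mitosis at 100 nM keep these transcripts, was not separately tested and stays open. On 1 of the 4 pairs of the same cluster and time the median was -0.50.

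The third pattern is the single clones called after docetaxel. Removing spots that disagreed with their pair or stood alone left 6 of the 18 calls with a value in every group (SEC31A, F2RL2, TRIB2, HMOX1, PLEK2 and SQSTM1), and all 6 were made again. For 5 of them no spot was removed, since their pairs all agreed, and PLEK2 lost 1 lone spot. The other 12 (6 that lost pairs that disagreed and 6 that lost lone spots) had no value left in a group. Being called again was thus fixed for the 5 and not open to the 12, so the test decides nothing and extreme single spots stay open. Between the untreated lines 887 of 955 were called again. Whether the calls follow docetaxel stays open.

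Other splits of the same arrays tell whether chance can be excluded. In MCF7 the real counts of changed clones were 0, which every split reaches, so these tests decide nothing: 100 of 100 at 100 nM (real 0, highest other 283), 100 of 100 at 4 nM (0, 858) and 100 of 100 between the doses (0, 4). For MDA-MB-231 counts as large came from 79 of 100 at 100 nM (1, 32), 28 of 35 at 2 nM (1, 11) and 29 of 56 between the doses (6, 24), and for the response of the lines to 100 nM from 68 of 100 (1, 274). For these 4 counts chance cannot be excluded, and the highest others were several times the real count. Whether a structure of the samples gave such counts was not shown. With splits within clusters and the cluster term the highest others were 6, 3 and 12 for the 3 MCF7 counts but still 35 for MDA-MB-231 at 100 nM (real 0 in each). Between the untreated lines only the real split, 1 of 100, reached its count (955, 16). The same held for the luminal list (1 of 100, with 2.03 and -1.22), so chance can be excluded for both. The clusters are not excluded as part of either difference, since these splits ignore them and only cluster 1 held both lines. With the cluster term the count was 622 of 5276 and the luminal median 0.89.

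For list medians, splits over all arrays and splits within clusters, with the cluster term, were set side by side. Both left chance open, at 5 in 100 or more, for 4 lists in MCF7. At 100 nM these were p53 (12 of 100; 0.21, highest other -0.30; within clusters 34 of 100; 0.16, -0.26) and G2/M (36 of 100; 0.21, 0.54; within 32 of 100; 0.26, -0.55). The others were replication at 4 nM (32 of 100; -0.19, 0.43; within 18 of 100; -0.19, 0.30) and G2/M between the doses (13 of 100; 0.40, -0.56; within 9 of 80).

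For 4 lists the 2 kinds of split differed, so whether chance can be excluded depends on the clusters and stays open. Replication at 100 nM in MCF7 had 17 of 100 (-0.26, highest other -0.44) but 4 of 100 within clusters (-0.26, 0.28). At 4 nM p53 had 10 of 100 (0.37, 0.65) but 4 of 100 within (0.37, -0.41), and G2/M 29 of 100 (-0.20, 0.42) but 1 of 100 within (-0.29, -0.28). Replication in MDA-MB-231 at 100 nM had 4 of 100 (-0.24, -0.34), but those splits ignore the clusters. Within clusters it had 1 of 12 (-0.23, -0.19), the least that 12 splits allow, and its list call ended with an estimated correlation (adjusted p = 0.32).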

How the results depend on the processing

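The cluster term, leaving out the 6 sparse arrays and removing disagreeing spots were chosen only after results were seen. Across the alternatives, 178 of 228 counts stayed within 1.5 times, and 3114 of 3277 gene values and 504 of 616 list values kept direction and side of the threshold. Leaving out single arrays, 112 of 160, 2397 of 2529 and 322 of 384 did. In the alternatives and the leave-one-out fits, 47 and 32 gene calls and 111 and 61 list calls were lost. Gene calls gained numbered 12 and 20, and 103 and 80 gene values without a call changed sign. Over 15 settings the p53 median at 4 nM stayed between 0.30 and 0.37 (1 call lost), replication at 100 nM in MCF7 between -0.41 and -0.20 (1 lost) and at 4 nM between -0.47 and -0.19 (1 lost). No scaling or centring moved the median of all clones by more than 0.05. MDA-MB-231 at 100 nM, alone, against 2 nM or against MCF7, had no value with the sample in Cy5 only, without the sparse arrays or without its 8 h array, and its 2 nM comparisons none without any 2 nM array. Where leaving out an array left 1 array at a time, that array was assumed to vary like the others. Signal over background was not analysed here, so what it limits is unknown. The cause was not tested for any change below, except that fewer clones or arrays enter the settings named for them.

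With an estimated correlation, calls ended for p53 (0.21, adjusted p = 0.064) and G2/M (0.21, 0.68) at 100 nM and G2/M at 4 nM (-0.20, 0.37) in MCF7, G2/M between those doses (0.40, 0.42) and replication in MDA-MB-231 at 100 nM (-0.24, 0.32). With fry on clones with values on all arrays they ended for p53 (0.21), G2/M (0.19) and replication (-0.31) at 100 nM, p53 (0.35), G2/M (-0.19) and replication (-0.19) at 4 nM, G2/M between the doses (0.34) and replication in MDA-MB-231 (-0.28). G2/M at 100 nM in MCF7 also lost its call with arrays scaled to the same spread (0.17), clones on all 31 arrays (0.19), arrays of the line only (0.19) and array weights (0.13).

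With the letter as a replicate block, counts were 5 (not 1) for MDA-MB-231 at 100 nM, 15 (not 1) at 2 nM, 2 (not 1) for the interaction and 0 (not 1) for MCF7 at 100 nM 8 h. Under that block G2/M at 4 nM in MCF7 was -0.17 (adjusted p = 0.83), replication in MDA-MB-231 -0.15 (0.11), and interferon at 100 nM in MCF7 turned to -0.0141 (0.95). The heat shock difference between the lines was 0.18 under it (0.43). The calls of MAP3K1, IL2RB, CRAT, PXK, HMOX1, PLEK2 and SQSTM1 in MDA-MB-231 (adjusted p = 0.067 to 0.31) and of TSPAN7 in MCF7 (0.9999) also ended under it. The letters do not pair the arrays: arrays of the same letter had deviations with a median r of 0.084 (-0.76 to 0.84, 48 pairs, 20 over 0.1), and arrays of different letters -0.043 (116 pairs).

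Adding the cluster term gave counts of 0 (not 1) for MDA-MB-231 at 100 nM, 20 (not 1) at 2 nM and 622 (not 955, with 5276 clones tested) between the untreated lines. It gave 0 (not 1) for the interaction, 1 (not 0) for MCF7 at 4 nM 24 h and 9 (not 4) for MDA-MB-231 at 100 nM 48 h. FGG turned to -0.31 (adjusted p = 0.89). The correlation of the 100 and 4 nM effects in MCF7 was 0.21 with the cluster term (0.04 without), and turned to -0.41 (-0.68 to 0.09) with controls split between the doses.

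With clones on all 31 arrays, counts were 0 (not 1) for MDA-MB-231 at 100 nM, 0 (not 1) at 2 nM, 1 (not 6) between its doses and 442 (190 higher, 252 lower) between the lines. They were 0 (not 1) for the interaction, 0 (not 1) for MCF7 at 100 nM 8 h, and 0 and 0 (not 4 and 4) for MDA-MB-231 at 100 nM 24 and 48 h. With arrays of the line only they were 0 for MDA-MB-231 at 100 nM, 0 at 2 nM, 0 between its doses, and 0 and 1 at 100 nM 24 and 48 h. With disagreeing spots removed they were 0 for MDA-MB-231 at 100 nM, 0 at 2 nM and 0 at 100 nM 24 h, 0 for the interaction and 0 for MCF7 at 100 nM 8 h.

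With arrays scaled to the same spread, counts were 11 for MDA-MB-231 at 2 nM, 12 (10 higher, 2 lower) between its doses, 0 at 100 nM 24 h, 1 for MCF7 at 4 nM 48 h and 1 for 48 against 8 h at 100 nM. With array weights they were 9 for MDA-MB-231 at 2 nM, 1980 (874 higher, 1106 lower) between the lines, and 1 and 1 for MCF7 at 48 h in 100 and 4 nM. Without a dye term they were 29 between the doses in MDA-MB-231 and 1 for MCF7 at 100 nM 48 h. With clones of a gene averaged the count between the doses in MDA-MB-231 was 3. With no filter they were 5 for MDA-MB-231 at 2 nM, and for MCF7 at 100 nM 2 at 8 h and 1 for 48 against 8 h. With the sample in Cy5 only they were, for MCF7, 2 at 100 nM 8 h, 14 (4 higher, 10 lower) at 4 nM 8 h, and 1 and 11 for 48 against 8 h in 100 and 4 nM. Without the 6 sparse arrays they were 2 at 100 nM 8 h, 1 at 4 nM 24 h and 1 for 48 against 8 h at 100 nM.

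Leaving out each array in turn, counts in MCF7 ranged from 0 to 19 at 100 nM (19 without 100 nM 8 h B, 3 without 24 h B, 1 without 48 h B). At 4 nM the range was 0 to 2 (2 without 4 nM 8 h A, 1 without 24 h A, control D or control G). Between the doses it was 0 to 13 (13 without 100 nM 8 h B, 3 without 24 h B, and 1 without 48 h B or without 4 nM 8 h A or B, 24 h A or 48 h B). They ranged from 0 to 56 at 100 nM 8 h (56 without 8 h B, 2 without 8 h A, 0 without control B, C, D, E or F), 0 to 9 at 24 h (without 24 h B) and 0 to 4 at 48 h (without control D or 48 h B). At 4 nM they ranged from 0 to 38 at 8 h (38 without control G, 6 and 8 without 8 h A and B), 0 to 4 at 24 h (4 without 24 h B, 2 without A) and 0 to 6 at 48 h (6 without control D, 3 without 48 h B). For 48 against 8 h the range was 0 to 23 at 100 nM (23 without 8 h B, 1 without 48 h B) and 0 to 7 at 4 nM (7 and 5 without 8 h B and A, 2 without 48 h B).

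In MDA-MB-231 the ranges were 1 to 2 at 100 nM (highest without 48 h B), 1 to 4 at 2 nM (4 without control B, 2 without D) and 2 to 8 between its doses (2 without 48 h A). They were 2 to 7 at 100 nM 24 h (7 without 24 h B, 2 without control A or B) and 3 to 86 at 48 h (86 without 48 h B). The interaction ranged from 0 (without MCF7 8 h B or MDA-MB-231 24 h B or 48 h B) to 2 (without MCF7 24 h B), and the count went from 652 to 994 between the lines. List medians ranged from 0.15 to 0.32 for p53 and 0.10 to 0.31 for G2/M at 100 nM in MCF7, from -0.30 to -0.10 for G2/M at 4 nM and from 0.26 to 0.57 between the doses, with calls lost as given in the report. G2/M at 100 nM 48 h ranged from -0.67 to 8.3e-04, turning without 48 h A. Replication ranged from -0.43 to -0.19 at 100 nM in MCF7 and -0.30 to -0.20 in MDA-MB-231, p53 at 4 nM from 0.24 to 0.49 and the luminal list from 1.89 to 2.08, with no call lost.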

Other observations

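The last p53 and G2/M tests below were chosen only after their results were seen.

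Of the 24 lists, 7 passed in none of the 18 comparisons (cholesterol synthesis did, with the preset correlation only, in the low dose difference between the lines that was added later), which does not show that their genes stayed the same: between the untreated lines 4 oestrogen receptor targets rose and 1 fell. Actin cytoskeleton genes, which shape and move the cell, had medians from -0.18 to 0.26 over the 18 comparisons (smallest adjusted p = 0.18), and oxidative phosphorylation genes of the mitochondrial membrane from -0.17 to 0.22 (0.073). Genes of the unfolded protein response, which follows stress in the endoplasmic reticulum, had -0.18 to 0.30 (0.082), cholesterol synthesis -0.27 to 0.40 (0.088) and glycolysis -0.59 to 0.13 (0.086). Oestrogen receptor targets had -0.37 to 0.42 (0.11) and blood and immune cell markers -0.21 to 0.69 (0.15). The p53 list passed in 7 of 18, the G2/M list in 9 and the replication list in 11 with the preset correlation.

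AP-1 and immediate early genes, transcribed within minutes of many signals, passed only in MCF7 comparisons that include 48 h, and with an estimated correlation in none (adjusted p = 0.27 at 100 nM and 0.35 at 4 nM against controls). At 4 nM they lay above controls of the same cluster on 6 of 6 arrays (0.27 ± 0.20, SD), with EGR1 at 3.05 and FOS at 2.12 at 48 h (1.99 and 0.89 cluster-adjusted), neither past the threshold over the list alone (adjusted p = 0.12 and 0.22). At 48 h in 100 nM DUSP1 was at 1.45 and KLF4 at 1.75 (1.29 and 0.68 cluster-adjusted; adjusted p = 0.10 and 0.16 over the list alone). Histone genes between 48 and 8 h in 4 nM had a median of 1.54 over 8 genes (adjusted p = 0.0089, and 0.19 with an estimated correlation), and 0.75 with the cluster term. H4C3 was at 2.49 and H1-2 at 3.45, or 2.06 and 1.87 cluster-adjusted (adjusted p without that term over the list alone 0.037 and 0.039, over all genes 0.49 and 0.52). In MDA-MB-231 at 100 nM histone genes lay 0.61 ± 0.61 (SD) below controls of the same cluster, on 4 of 5 arrays.

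A p53 response limited to MCF7, whose p53 gene is intact, was examined at the low dose. The effect in MCF7 minus that in MDA-MB-231 had a median of 0.416 over 20 genes, 18 above 0 (adjusted p = 7.9e-07). With an estimated correlation adjusted p was 0.0015, and 0.039 with the cluster term as well (0.41). On arrays the p53 list lay 0.39 ± 0.43 (SD, n = 6) above controls in MCF7 and 0.15 ± 0.03 (SD, n = 3) below them in MDA-MB-231. This fits a difference between the lines, but the doses were 4 and 2 nM, so a difference in dose could give the same values. MDA-MB-231 at 100 nM had 0.19 ± 0.20 above controls on 5 of 5 arrays, which were set against controls C and D alone.

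The fall of the G2/M list between 8 and 48 h of 100 nM in MCF7 was tested against the array clusters. The median was -0.864 with the cluster term beside -0.871 without it, so a shift of whole clusters does not account for the fall. It rested on 1 array: without 48 h replicate A the median was -0.36 and the call ended (adjusted p = 0.20). Replicate A, in cluster 2, lay 0.62 below controls of its cluster, and replicate B, in cluster 3, lay 0.44 above control D, the only control there. Only cluster 2 held both times, so a response that differs between clusters was not tested and stays open.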
